A study of Homo sapiens with 2 samples.

How the data were processed

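The series holds 2 reduced representation bisulfite sequencing libraries of HCT116 cells, a human colon cancer cell line. The labels put 1 library in a control group and 1 in a group treated with H2O2 (hydrogen peroxide, an oxidant). The dose and the time of treatment were not given in the sources used here. Per the labels' protocols, genomic DNA was cut with the enzyme MspI, which cuts at CCGG whatever the methylation of the inner CpG, adapters were ligated, fragments were cut from a gel in short and long size fractions, and the DNA was treated with bisulfite in repeated rounds, amplified by PCR and sequenced. Bisulfite turns unmethylated cytosine into uracil and leaves methylated cytosine, so that reads can be counted as methylated or unmethylated at each cytosine.

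The authors deposited 1 table per library with a count of methylated reads and a count of unmethylated reads for each cytosine and strand; the values were whole numbers and were taken as raw counts. CASAVA 1.8, FastQC and the build hg19 are named in the submitters' processing notes. The aligner and the methylation caller are not given in the sources used here, nor is any removal of duplicate reads. Both deposited tables listed the same 41227555 cytosines in the same order, which formed 657814 MspI fragments of 40 to 220 bp with filled-in ends. The CpGs of the MspI sites themselves were not listed. A further deposited column behaved like the number of genome positions a read matched and is called the hit number here; its meaning was not stated, and a last column was not used. Counts reached at most 9995 in the control library and 9993 in the H2O2 library, so the deepest cytosines appear capped. Positions are given as the files give them, in hg19, and were taken to count from 1.

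Depth was 582087575 cytosine calls in the control library and 564721508 in the H2O2 library, of which 81896537 and 79725887 were at CpGs. No read covered 18.7% of the listed cytosines in the control library and 18.0% in the H2O2 library. Reads of both strands of a CpG were summed, and CpGs with at least 10 reads in both libraries were kept, 1955492 of 2788983 listed (70.1%), with a median of 34 reads per CpG in the control library and 33 in the H2O2 library. Intervals of single levels are Wilson 95% intervals. Intervals of mean differences are 95% percentile intervals from 1000 bootstrap draws of 1 Mb blocks. All of them cover counting error or the choice of sites only: PCR copies are not independent molecules, and no interval here covers the spread between cultures.

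With 1 library per group there was no replicate check, and each test compared the reads of 2 libraries, not the conditions. Each CpG was tested with a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a difference of at least 25 percentage points (points below). Non-overlapping 500 bp tiles with at least 3 such CpGs were tested on summed reads and called at 10 points. One read can cover several CpGs of a tile, so that summed reads overstate the evidence. CpGs with at least 10 reads on each strand in both libraries were used to compare the strands, whose reads come from separate molecules. A tile was called CpG-dense where the listed fragments in it had a CpG observed-to-expected ratio of at least 0.6 and a GC content of at least 50%. The plan named dense and sparse tiles without giving these limits. The tests and call thresholds were fixed before the data were examined, as was the rule for named items. That rule took the 5 CpGs and 5 tiles most different in each direction among calls with at least 30 reads in both libraries.

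The tests were tested on simulated data with the real depths, in which 200 CpGs or tiles were changed by known amounts. Of CpGs changed by 50 points, 37% were called over 1955492 CpGs, with 0 false calls, and 8 of the 200 changed by 30 points. Of tiles changed by 30 points, 84.5% were called over 202034 tiles, with 1 false call, and 21% of those changed by 15 points, with 2 false calls. These simulations drew each read independently, and those of tiles used the depth of summed reads. Alternatives covered the read minimum, the deepest CpGs, strands, tile size, thresholds, an overdispersed test, thinning, and other ways of counting tile reads. Thinning cut the library with more reads at a CpG to the depth of the other, in a single random draw. The deeper library named below is thus set for each CpG. The closing section gives the effect of the alternatives. Promoter tests and tests of gene lists (antioxidant, DNA repair, methylation enzyme, colorectal cancer marker, p53, imprinted, housekeeping, germline, developmental and cell type marker genes) had been planned, but the gene table at hand is of another build (GRCh38), so they were not run and no gene is named by position. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.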

Results

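The methylomes of control and H2O2-treated HCT116 cells were compared at 1955492 CpGs in MspI fragments, with 1 library per group. The comparison addressed whether H2O2 treatment of these colon cancer cells went with different CpG methylation, over the genome and at single sites. Most CpGs were either unmethylated or highly methylated in both libraries. The mean CpG level was 62.1% in the control library and 61.9% in the H2O2 library. Site levels of the libraries correlated with a Pearson r of 0.987 and a Spearman rho of 0.828 across CpGs, which are not independent replicates. There was no replicate of either group, so no difference below could be set against the spread between cultures.

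In the control library 31.0% of CpGs were under 20% methylated, 10.1% were between 20 and 80%, and 58.9% were over 80%. In the H2O2 library the shares were 31.1%, 10.3% and 58.7%. The level was equal in both libraries at 33.7% of CpGs, higher in the H2O2 library at 32.3% and lower at 34.0%. The levels lay within 10 points of each other at 88.3% of CpGs and within 25 points at 98.9%. The mean site difference, H2O2 minus control, was -0.190 points (95% bootstrap interval -0.205 to -0.175), and the median was 0.

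**Figure D1:**
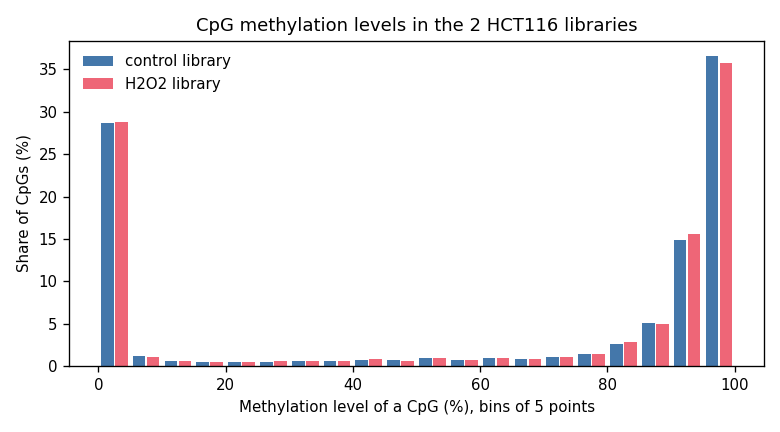
Share of CpGs (y axis, percent) by methylation level (x axis, percent, bins of 5 points) in the control library (blue) and the H2O2 library (red), over 1955492 CpGs. Both libraries have one peak near 0 and one near 100, with 31.0% of control CpGs under 20% and 58.9% over 80%.

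The level pooled over all reads differed more than the mean of site levels. Of all CpG reads at these sites, 61.8% were methylated in the control library (Wilson interval 61.8 to 61.8) and 58.8% in the H2O2 library (58.8 to 58.8), a difference of -3.02 points. Levels at fixed depth accounted for -0.207 points of this difference and the different spread of depth over sites for -2.81 points. CpGs under 10% methylated took a larger share of the reads in the H2O2 library, by a log2 ratio of 0.14, and CpGs of 90 to 100% a smaller one, by a log2 ratio of -0.08.

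**Figure D2:**
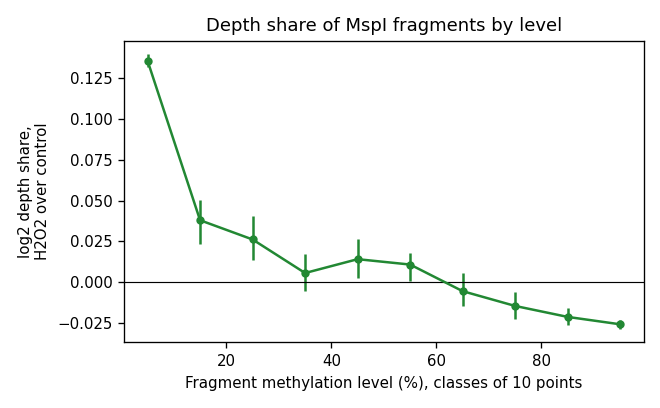
Mean log2 ratio of the depth share of MspI fragments, H2O2 over control (y axis), by fragment methylation level (x axis, percent, classes of 10 points). Points are means, bars 95% block bootstrap intervals. The ratio was 0.14 for fragments of 0 to 10%, 0.04 for those of 10 to 20% and -0.03 for those of 90 to 100%.

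Every chromosome from 1 to 22 and X had a lower mean site level in the H2O2 library. The difference on these 23 chromosomes ranged from -0.265 points on chromosome 2 to -0.129 points on chromosome X, and the bootstrap interval lay below 0 on all 23. Chromosome Y, with 351 CpGs and no interval, went the other way, from 56.0% to 57.1%, and the 14 CpGs of the mitochondrial genome differed by -0.525 points. Pooled levels differed by -3.31 points on chromosome 6 and by -2.64 points on chromosome X, the extremes among them. Control levels ranged from 59.1% on chromosome 3 to 67.3% on chromosome 21. Chromosome X had a mean level of 59.8% in the control library and 59.7% in the H2O2 library, with a median of 21 and 20 reads per CpG against 34 and 33 on the autosomes. Chromosome 8 had the highest median depth among chromosomes 1 to 22 and X, 46 reads in each library, followed by chromosome 17 with 39 and chromosome 16 with 36.

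**Figure D3:**
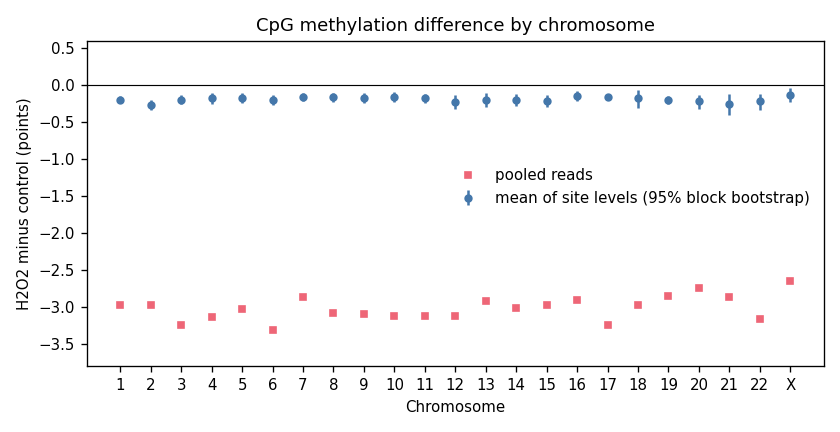
Difference in CpG methylation, H2O2 minus control (y axis, points), for chromosomes 1 to 22 and X (x axis). Blue points are means of site levels with 95% block bootstrap intervals, red squares are levels of pooled reads. Means of site levels lie between -0.265 and -0.129, pooled levels between -3.31 and -2.64.

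CpG-dense tiles were less methylated than CpG-sparse tiles in both libraries. The 1174276 CpGs of dense tiles had a mean level of 48.8% in the control library and 48.6% in the H2O2 library, a difference of -0.219 points (-0.240 to -0.198). The 781216 CpGs of sparse tiles had 82.2% and 82.0%, a difference of -0.147 points (-0.166 to -0.128). Pooled over reads, the differences were -3.76 points in dense and -0.713 points in sparse tiles. In dense tiles 45.8% of CpGs were under 20% methylated in the control library and 45.9% in the H2O2 library, against 8.75% and 8.79% in sparse tiles. CpGs with a hit number over 1 were highly methylated, at 85.6% in the control library and 85.4% in the H2O2 library. CpGs with a hit number of 1 had 57.6% and 57.4%. Fragments of up to 120 bp took a larger share of reads in the H2O2 library (log2 ratio 0.08) and longer ones a smaller share (log2 ratio -0.09). The bases next to a CpG went with its level: the mean in the control library was 71.4% at TCGA and 55.5% at GCGG, and the difference between the libraries was between -0.229 and -0.161 points in all 15 contexts.

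The difference by level depended on how CpGs were classed. Classed by the mean of both libraries, a classing chosen after seeing the data, CpGs of 40 to 60% had 51.0% in the control library and 49.2% in the H2O2 library, a difference of -1.77 points (-2.001 to -1.55, 66481 CpGs). CpGs of 90 to 100% differed by -0.0661 points (-0.0771 to -0.0553) and CpGs under 10% by -0.0360 points (-0.0422 to -0.0296). Classed by the control level alone, which had been fixed before the data were examined, CpGs under 20% differed by 0.190 points (0.176 to 0.204), those of 20 to 80% by 0.881 points (0.759 to 1.002) and those over 80% by -0.575 points (-0.591 to -0.560). Classed by the H2O2 level, the same 3 classes differed by -0.332, -3.06 and 0.387 points. The signs thus turned with the library that set the class.

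**Figure D4:**
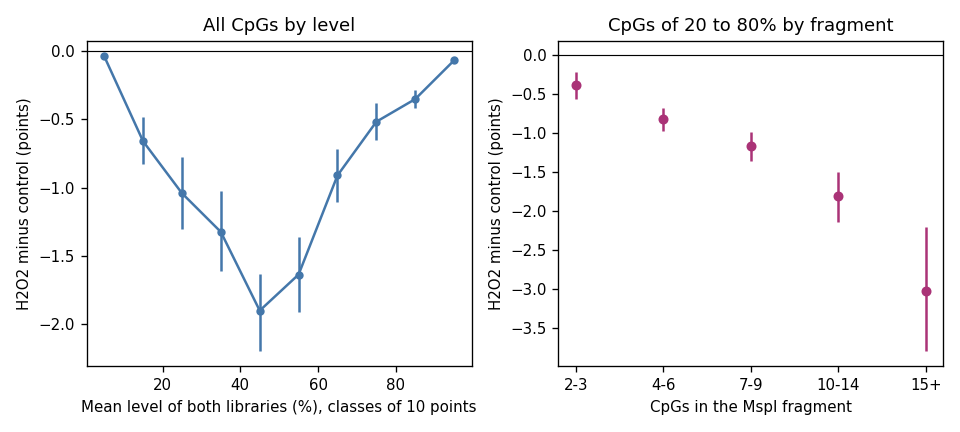
Difference in CpG methylation, H2O2 minus control (y axes, points). Left, all CpGs by the mean level of both libraries (x axis, percent, classes of 10 points), lowest at 40 to 50% with -1.90 points; right, CpGs of 20 to 80% by the number of CpGs in their MspI fragment (x axis), from -0.384 points with 2 to 3 CpGs to -3.02 points with 15 or more. Bars are 95% block bootstrap intervals.

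Cytosines outside CpGs were almost unmethylated in both libraries. Of their reads, 0.129% were methylated in the control library (Wilson interval 0.129 to 0.129) and 0.123% in the H2O2 library (0.123 to 0.123). This level is an upper limit for unconverted cytosine. CHG cytosines had 0.105% and 0.101%, and CHH cytosines 0.141% and 0.134%. The mitochondrial genome, at 164 non-CpG cytosines, had 0.0720% (0.0672 to 0.0771) in the control library and 0.0421% (0.0384 to 0.0461) in the H2O2 library. Its 14 CpGs had 1.07% (1.02 to 1.12) and 0.663% (0.622 to 0.706), from counts that included capped ones.

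At single CpGs, 14 were called higher and 17 lower in the H2O2 library out of 1955492 tested (Fisher's exact test, two-sided, Benjamini-Hochberg). These 31 CpGs lay on 28 fragments of 15 chromosomes, and all had a hit number of 1. Of the 31, 20 lay in dense tiles, which held 60.05% of all tested CpGs. An overdispersed test left 0 calls in either direction. Its extra spread was estimated from the strand differences within each library. These had 2.06 (control) and 1.91 (H2O2) times the binomial variance, against 1.398 between the libraries at CpGs of 20 to 80%. That test may thus be too strict, and its power was not simulated, so its 0 calls cannot decide whether the calls are real. Without the minimum difference, 48 CpGs passed the adjusted p, 14 higher and 34 lower. At an unadjusted p under 0.05 there were 51028 CpGs (2.61%), against 1.06% on average in 10 redraws of the same reads between the libraries, which gave 0 calls.

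The CpG on chromosome 1 at 160385883 to 160385884 had 41.3% of 75 reads methylated in the control library (30.9 to 52.6) and 92.5% of 40 reads in the H2O2 library (80.1 to 97.4), exact test, adjusted p = 0.00685. On chromosome 19, the CpG at 2457364 to 2457365 rose from 42.4% of 66 reads to 84.8% of 79 reads (exact test, adjusted p = 0.0105). The CpG on chromosome 17 at 20460606 to 20460607 rose from 30.9% of 110 reads to 70.8% of 96 reads (exact test, adjusted p = 0.00369). That on chromosome 5 at 1201713 to 1201714 rose from 53.03% of 66 reads to 92.4% of 79 reads (exact test, adjusted p = 0.00881). On chromosome 19 at 53635901 to 53635902, the level was 62.9% of 70 reads and 100% of 44 reads (exact test, adjusted p = 0.0253), with 0 reverse-strand reads in the control library.

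Among called CpGs with at least 30 reads in both libraries, the largest fall was on chromosome 12 at 52208311 to 52208312, from 76.1% of 46 reads (62.1 to 86.1) to 26.3% of 57 reads (16.6 to 39.0), exact test, adjusted p = 0.0318. The CpG on chromosome 8 at 24858278 to 24858279 fell from 93.0% of 43 reads to 48.4% of 64 reads (exact test, adjusted p = 0.0397). On chromosome 6 at 41701351 to 41701352, the level was 88.0% of 75 reads and 48.1% of 54 reads (exact test, adjusted p = 0.0468), with 1 reverse-strand read in the H2O2 library. A further CpG on chromosome 8, at 143575306 to 143575307, fell from 57.5% of 87 reads to 18.1% of 83 reads (exact test, adjusted p = 0.0130). The CpG on chromosome 20 at 57464195 to 57464196 fell from 63.4% of 101 reads to 26.7% of 86 reads (exact test, adjusted p = 0.0318). Larger differences were called at lower depth in both directions, at CpGs named after their values were seen. The CpG on chromosome 11 at 705160 to 705161 rose from 0% of 22 reads to 75% of 16 reads, and that on chromosome 14 at 36278345 to 36278346 differed by -74.1 points, with 26 and 19 reads and the same counts at CpGs beside it (exact test, adjusted p = 0.0355 each). Each of these adjusted p-values is from Fisher's exact test on the reads of 2 libraries. Of the 10 CpGs with at least 30 reads named here, 6 lost their call when the library deeper at each CpG was thinned.

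The differences on the strands of a CpG, read from separate molecules, were not correlated. Over 785493 CpGs, the correlation of the forward and reverse difference was -0.000382 (Spearman rho -0.00116). For the 74734 CpGs of 20 to 80% it was -0.00182, with a standard deviation of 16.9 points on each strand. The covariance of the strands (-0.521, bootstrap interval -3.61 to 2.83) allowed a difference common to both strands with a standard deviation of at most 1.68 points. Of 12 CpGs past the threshold on the forward strand alone, 5 had the same sign on the reverse strand (41.7%, exact 95% interval 15.2 to 72.3). In wider selections at an unadjusted p under 0.001 and 25 points, chosen after seeing the data and without CpGs of 0 difference on the other strand, 290 of 576 CpGs selected on the forward strand had the same sign on the reverse strand (50.3%, exact p = 0.901), but 350 of 621 selected on the reverse strand had the same sign on the forward strand (56.4%, exact p = 0.00173). Both exact tests counted CpGs as separate trials, although CpGs of 1 fragment share reads, so these p-values may be too small. Of the 31 calls, 22 had at least 5 reads on each strand in both libraries and 21 of these had the same sign on both, but they had been selected on the sum of the strands.

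**Figure D5:**
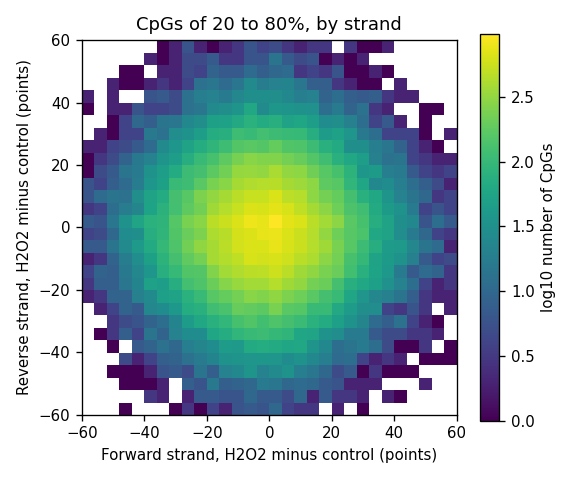
Difference in methylation, H2O2 minus control, on the forward strand (x axis, points) and the reverse strand (y axis, points) of the 74734 CpGs of 20 to 80% with at least 10 reads on each strand in both libraries. Colour is the log10 number of CpGs per square of 4 points; axes are limited to 60 points. The cloud is round, with a correlation of -0.00182.

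Of 202034 tiles of 500 bp, 261 were called higher and 685 lower in the H2O2 library (Fisher's exact test on summed reads, Benjamini-Hochberg). Summed reads weight CpGs by depth, so a called tile need not differ in its mean site level. An example chosen after seeing the data is the tile on chromosome 1 from 226099001 to 226099500. It differed by -14.4 points in summed reads and by 2.13 points in mean site level. The number of such tiles was not counted. When reads were counted once per fragment strand, an alternative chosen after seeing the data, 0 tiles were called in either direction. Then 1 tile passed the adjusted p at any size, and 0.938% of tiles had an unadjusted p under 0.05. The median tile had 50 such reads in the control library, against 204 summed reads. Power at this depth was not simulated, so the 0 calls cannot decide whether the called tiles are real. Dividing a tile's reads by its CpG number also left 0 calls, but it counts too few reads where a tile holds several fragments, and 0.112% of tiles then had an unadjusted p under 0.05. Sign flips over the CpGs of a tile gave 20 higher and 135 lower. They take CpGs that share reads as separate units, so they overstate the evidence as summed reads do. In the other direction, a tile of few CpGs has few possible flips and cannot reach a small p. The median tile had 6 CpGs, so the fall in the counts does not show that the lost calls were false. On each strand, 84 and 318 called tiles also passed an unadjusted p of 0.05 on summed reads. This rule was chosen after seeing the data, in tiles already selected on both strands. Strands were also compared with reads counted once per fragment strand, in 126282 tiles with at least 10 on each strand in both libraries. Their differences had a correlation of 0.00707, and of 0.0122 in the 16781 tiles of 20 to 80% (covariance interval -0.457 to 2.63). Of the 126282 tiles, 49 were selected on the forward strand at an unadjusted p under 0.001 and 10 points, a test chosen after seeing the data. On the reverse strand, 32 of the 49 had the same sign (65.3%, exact 95% interval 50.4 to 78.3, exact p = 0.0444). No selection on the reverse strand was run for tiles. Tile levels correlated with an r of 0.994 across tiles. Of the called tiles, 624 had levels of 20 to 80% in both libraries and 669 were CpG-dense. These numbers were not set against the shares among all tested tiles.

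The tile on chromosome 4 from 46726501 to 46727000 had 45.8% of 96 CpG reads methylated in the control library and 100% of 60 in the H2O2 library, all from 1 strand. Neighbouring tiles on chromosome 6, from 26570001 to 26570500 and from 26570501 to 26571000, had 28.8% against 74.1% (62.2 points forward, 20.03 points reverse) and 29.9% against 76.8% (64.4 and 25.7 points). The tile on chromosome 16 from 15528501 to 15529000 had 24.02% of 512 reads and 67.5% of 286 reads, with opposite signs on its strands (47.1 points forward, -21.2 points reverse). The tile on chromosome 17 from 43973001 to 43973500 had 25% of 112 reads and 68.1% of 138 reads (31.0 and 51.9 points). In the other direction, the tile on chromosome 9 from 115818501 to 115819000 had 85.2% of 176 reads in the control library and 36.6% of 186 in the H2O2 library (-67.1 and -40.2 points). The tile on chromosome 7 from 20826501 to 20827000 had 100% and 51.8%, mostly from the reverse strand (-11.4 points forward, -75 points reverse), and that on chromosome 6 from 163835501 to 163836000 had 96.3% and 49.7% (-48.2 and -41.6 points). Tiles on chromosome 8 from 77593001 to 77593500 and on chromosome 15 from 51387001 to 51387500 had 46.2% and 45.5% in the control library and 0% in the H2O2 library, from 52 and 30 reads summed over 4 and 3 CpGs, which are not separate molecules and set no limit on the level. The strands could not be compared in either, since the former had 0 forward reads in the control library and the latter 0 reverse reads in both libraries. With a minimum of 5 reads per CpG, which adds CpGs, the difference of the chromosome 8 tile was -26.2 points in place of -46.2 (Fisher's exact test, adjusted p = 0.0304). None of these 10 tiles was called when reads were divided by CpG number or counted once per fragment strand.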

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

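No paired analysis was possible because each group had 1 library and the labels gave no shared numbers. The hit number, the calls on each strand, the classes by mean level, the unadjusted selection by strand and the reads counted once per fragment strand were tried only after seeing the data; the others had been chosen before. Of 88 alternative values, 38 stayed within their margin or on their side of the threshold, 19 moved in the same direction, 24 counts fell and 2 rose by over 1.5 times, and 5 values turned. Promoter and gene list alternatives were not run, for want of an annotation of the build. The pooled difference of -3.02 points was -3.16 at 5 reads, -2.76 at 20, -2.48 at 30, -3.11 without the deepest CpGs, -2.64 with strands as sites, -3.28 at hit number 1, -3.04 on autosomes and -0.190 as the mean of site levels, where depth does not enter.

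CpGs called higher and lower, 14 and 17, were 8 and 6 without the deepest CpGs, 5 and 3 with the deeper library thinned, 4 and 0 at an adjusted p under 0.01, 8 and 6 when also past an unadjusted p of 0.05 on each strand, and 0 and 0 with the overdispersed test. Strands as sites gave 9 higher. No minimum difference gave 34 lower. Tiles, 261 and 685, were 161 and 421 at 30 reads, 42 and 63 at 25 points, 20 and 135 with sign flips over CpGs, 84 and 318 on each strand, and 0 and 0 with reads divided by CpG number or counted once per fragment strand; an adjusted p under 0.01 gave 164 higher. A lower adjusted p, a larger minimum difference and a further condition on each strand can only lower a count. A minimum of 30 reads lowered the counts of tiles and raised those of CpGs, to 18 and 26. Sign flips cannot reach a small p in tiles of few CpGs. Power was not simulated for the alternatives that left 0 and 0.

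The share of same signs, 41.7%, was 50.3% for 576 CpGs selected at an unadjusted p under 0.001 on the forward strand (exact p = 0.901) and 56.4% for 621 selected on the reverse strand (exact p = 0.00173). These exact tests took CpGs that share reads as separate trials. Pooled reads gave -3.76 points in dense and -0.713 in sparse tiles. For control levels under 20%, the difference was 0.263 at 5 reads, 0.108 at 20 reads, 0.0462 pooled and -0.0591 by mean level. For 20 to 80% it was 1.68, 0.0366, -0.0784 and -1.19. Over 80% it was -0.752, -0.399, -0.463 and -0.0962. A class set by 1 noisy library moves toward the other by construction, less so with more reads. Of 51 tested values of named CpGs and tiles, 34 kept their call, 17 lost it and 0 turned; 10 of the losses were tiles with reads divided by CpG number and 6 were CpGs with the deeper library thinned. These 6 were the named CpGs on chromosomes 6, 12, 19 (both) and 20 and that at 24858278 on chromosome 8, with differences of -35.2, -52.2, 40.9, 34.1, -37.2 and -46.5 points (exact test, adjusted p = 0.766, 0.0742, 0.0939, 0.300, 0.0885 and 0.148). The CpG on chromosome 6 also lost its call at 5 reads, its difference unchanged (exact test, adjusted p = 0.0528). The 51 values leave out the overdispersed test and reads counted once per fragment strand, under which no CpG and no tile, respectively, was called. The means of site levels of the 10 named tiles, not tested, kept their sign, but these tiles have the largest differences. Some other called tiles changed sign, such as that on chromosome 1 from 226099001, with -14.4 points in summed reads and 2.13 in mean site level. Depth limits single CpGs: 8 of 200 simulated changes of 30 points were called.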

Other observations

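The tests of conversion, of loss in proportion to the level, of levels at fixed depth, of GC over both strands and of multi-copy fragments were chosen only after the result was seen. The single-strand test had been fixed before the data were examined, but its use to weigh an explanation was chosen after. Some cytosines outside CpGs read as methylated in both libraries. With at least 10 reads in both, 7070 had at least 50% methylated reads in the control library and 7061 in the H2O2 library, and 5970 did so in both, 84.4% of those in the control library. Of these, 4639 had a hit number of 1. They made up 0.0914% of the cytosines of any hit number compared in the trinucleotide CAT, 0.0796% in CCC, 0.0671% in CAC, 0.0475% in CAA and 0.0370% in CAG. Contexts were taken as deposited, and differences of these cells from the build, which could change a context, were not examined. A further 17 CpGs, all lower in the H2O2 library, passed the adjusted p with less than 25 points of difference. Of these 17, 8 lay on 1 fragment of chromosome 20, from 26188828 to 26188907, where the CpG at 26188905 had 59.4% of 10618 reads in the control library and 55.1% of 10208 in the H2O2 library. Another 4 lay on the mitochondrial genome, whose counts included capped ones, and 3 on chromosome 1. Those on chromosomes 1 and 20 had at least 10201 reads in each library, so their counts may include capped ones too. Of the 17, all but the CpG on chromosome 4 at 53314 (240 and 312 reads) had at least 6423 reads in each library. These deep CpGs differed by only -6.31 to -0.646 points, since small differences can pass the adjusted p at such depth. The CpGs on chromosomes 1 and 7 had hit numbers over 1 in both libraries. CpGs of 1 fragment share reads, so the 17 are not separate evidence of lower methylation.

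The pooled CpG level was lower in the H2O2 library. Level differences at fixed depth, whatever their origin, made up 6.87% of this, which argues against loss of methylation at the CpGs themselves as the main part. In a linear fit, the log2 depth ratio of fragments, H2O2 over control, fell by 0.16 from 0 to 100% methylated. The fall was uneven: the mean ratio was 0.136 at 0 to 10%, 0.038 at 10 to 20% and -0.026 at 90 to 100%. Of the linear slope, 91.8% was kept with fragment length in the model and 84.7% with GC content and CpG number, so that neither carries most of it. A loss of GC-rich converted strands would lower the strand with more guanine in unmethylated fragments, as written before the test. This was met, with a slope of -0.0600 per 10 points (-0.0681 to -0.0522), and of -0.142 (-0.148 to -0.137) in methylated fragments. Such a loss would also lower GC-rich fragments, but in a test added afterwards the depth ratio of unmethylated fragments rose by 0.0809 per 10 points of GC at fixed length (0.0772 to 0.0839). The added test compares different fragments, where another effect of GC on both strands could hide such a loss. These tests thus cannot decide how large a part it has. The cause of the depth difference stays open, a difference between the library preparations and the treatment being confounded with 1 library each.

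Classed by the mean of both libraries, a classing chosen after seeing the data, CpGs of intermediate level were lower in the H2O2 library. In the planned class by control level, those of 20 to 80% were higher by 0.881 points (0.759 to 1.002), so what follows holds for the former classing. The shift at 40 to 60% was 302 times the difference of non-CpG levels, which argues against a difference in conversion of unmethylated cytosine. Conversion of methylated cytosine does not show in non-CpG levels and was not tested. At 90 to 100% the difference was -0.0661 points, which argues against a loss in proportion to the level. Lower recovery of methylated molecules in the H2O2 library is a candidate explanation: the log2 odds fell further with more CpGs per fragment, by a slope of -0.105 per 10 CpGs (-0.130 to -0.0824). The slope was -0.193 (-0.225 to -0.162) with classes by control level and -0.0292 (-0.0560 to -0.00249) with classes by H2O2 level, both tested after seeing the data. The mean log2 odds ratio was -0.03 with 2 to 3 CpGs and -0.19 with 15 or more, and the differences in level were -0.384 and -3.02 points. A real loss in CpG-rich fragments of intermediate level may give the same slope and was not tested.

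For the called CpGs, chance variation of single strands and real differences cannot be told apart. Of 12 CpGs past the threshold on the forward strand, 5 had the same sign on the reverse strand (41.7%, exact 95% interval 15.2 to 72.3), too few to decide. Within a library the strands differed with 2.06 (control) and 1.91 (H2O2) times the binomial variance, against 1.398 for the difference between the libraries at CpGs of 20 to 80%. Independent reads alone would not do, since redraws gave 0 calls. At an unadjusted p under 0.001 and 25 points, CpGs selected on the forward strand had the same sign in 50.3% and those selected on the reverse strand in 56.4% (exact p = 0.901 and 0.00173). Their exact intervals overlap, 46.2 to 54.5 and 52.4 to 60.3, and their difference was not tested. These tests and intervals take CpGs of 1 fragment, which share reads, as separate trials and may overstate the evidence. Multi-copy or capped fragments are argued against as the place of the calls: all 31 calls had a hit number of 1 and lay outside the deepest CpGs, and 24 of 31 (77.4%) remained after a new adjustment without such CpGs. Leaving out the deepest CpGs alone left 8 higher and 6 lower, under the majority that was the limit of this test, so the number of calls depends on the deepest CpGs through the adjustment.

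Changes over 1 Mb regions were tested as a hypothesis by splitting the fragments of 2603 windows alternately into a pair of sets, after taking out the mean difference of each level class. The sets correlated with a Pearson r of 0.0384 (bootstrap interval -0.0263 to 0.106, permutation p = 0.0518; Spearman rho 0.0346), and 0.0391 without the 2 windows farthest from the median. The bound set beforehand, an interval that includes 0, was met, but such an interval does not exclude a small correlation, so regional changes cannot be told apart from none at this depth.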
